A study of Danio rerio with 37 samples.

How the data were processed

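RNA was measured by sequencing in the gills of 37 adult zebrafish, 1 library per fish per the labels. The labels name 9 control diet uninfected, 9 control diet infected, 10 inulin diet uninfected and 9 inulin diet infected libraries. The deposited values are read counts per Ensembl gene, not normalised, with 1 column per library. The genome build GRCz11 and the tool DESeq2 are named in the submitters' processing notes, with no version. The aligner, the counting program, its use of strand and the annotation release are not given in the sources used here. Even low values were more frequent than odd ones in the deposited counts: the value 2 filled 14485 cells and the value 1 filled 4694. A count is therefore taken as a read and not as a fragment, as where both reads of a pair are counted. The table held 25431 genes, after 15 lines of annotation text without counts were dropped. Gene symbols came from the deposited table, and where these were blank or shared, from a table of Ensembl gene names that matched 23607 of the gene identifiers. No coordinates were used. Reads of near-identical gene copies, of overlapping genes and of antisense partners could have been split or merged by the counting, so values of such copies are uncertain.

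Library depth was 26763244 to 34338355 counts. Gene levels are given as CPM, the counts of a gene per library total in the usual scaling of edgeR, with TMM factors, except that transcripts used to find other tissues in single libraries (such as myl7) are CPM without TMM factors. No pair of libraries within a group was identical, and the chi-square of their counts per degree of freedom was at least 51.4, so each library was counted as 1 replicate. The p-values measure the spread between fish within a group. Tank and hour of sampling are not in the labels, so a shared tank effect cannot be separated from a group.

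Counts were analysed in R 4.3.3. Genes were kept by the default expression filter of edgeR 4.0.16 applied by group, which left 20199 genes, and libraries were scaled by trimmed mean of M values (TMM). A negative binomial model with 4 group means was fitted to all 37 libraries, and contrasts were tested by the edgeR quasi-likelihood F test with robust estimation. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a false discovery rate of 0.05 and no fold threshold. The 7 contrasts were infection on each diet, inulin in each infection state, both effects averaged over the other factor, and their interaction. Log2 fold changes are given with a standard error computed from the F statistic. Log2 CPM values used a prior count of 2, and the fold change of a gene with almost no counts in 1 group depends on that kind of prior. Some of the largest of such folds are given beside the CPM of both groups, and others without CPM.

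Gene lists for pathways, gill cell types and other tissues, 45 in all, were written before the data were examined, and each had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list with all other genes, adjusted over the 45 lists. The same test with an estimated correlation and the fry rotation test were alternatives. Counts of list members that passed are also given adjusted over the list alone. Some lists share members, at most 4 for a pair of lists.

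The genes named in the text were chosen by a rule also fixed before the data were examined. For each contrast between 2 groups, it takes the 10 largest changes in each direction among passing genes of at least 5 CPM in the higher group, and up to 4 members with the smallest adjusted p of each list. It adds 18 genes named whatever their result and, where fewer than 5 genes pass, the 5 with the smallest p. For the interaction it takes the genes past the threshold, up to 10. Genes need a symbol that is not a clone or locus placeholder. The text describes a part of those genes and says where it goes outside the rule.

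Group differences in library measures were tested by two-sided exact permutation tests over all regroupings, adjusted over the 6 pairs of groups for each measure. Each edgeR contrast was checked on simulated counts of the tested genes, with 50 genes changed at each of 4 fold sizes. For inulin in uninfected fish it recovered 54% of genes changed 2-fold and 94% of those changed 8-fold, with 7 false calls among 19632 unchanged genes. For the interaction it recovered 28% and 84%, with 4 false calls among 19653.

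Alternatives planned before the data were examined were median-ratio scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma voom with quality weights, a false discovery rate of 0.01, a fold threshold, fits of the compared groups only, the replicate number as a block, the library round as a covariate, a fit without 6 libraries listed out of number order, and 1 surrogate variable from sva 3.50.0. Library round means that library numbers ran through the groups once up to number 31 and again from number 32. A further 5 alternatives were chosen after seeing the data: fits without 6 libraries with a TMM factor under 0.9, without inulin diet infected library 2, without control diet uninfected library 9, and without 9 libraries with the heart transcript myl7 above 10 CPM, and a fit of halved counts. Each count of genes was compared with 100 splits of the libraries, the real split included.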

Results

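Gill transcriptomes of adult AB wildtype zebrafish were compared in a design that crossed diet with a parasite. Fish received a control diet or a diet with 20% inulin, a plant fructan that vertebrates do not digest and that gut bacteria ferment, for 35 days. Part of each diet group was then exposed to 4000 parasites per fish of Ichthyophthirius multifiliis, a ciliate that burrows into the skin and gills of freshwater fish, and gills were sampled 5 days later. The series asks whether changes of the gut microbiome brought about by diet alter how fish cope with the parasite. The 37 gill libraries comprised 9 control diet uninfected, 9 control diet infected, 10 inulin diet uninfected and 9 inulin diet infected fish. Total counts per library were 29302311 to 33006899, 27694964 to 33909043, 27913904 to 34338355 and 26763244 to 33967764 in that order. No difference in depth between groups passed (lowest exact permutation p = 0.663, two-sided, adjusted p = 0.957).

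The mitochondrially encoded share of counts was 6.62 ± 1.51% (SD, n = 9) in control diet uninfected, 5.34 ± 0.98% (n = 9) in control diet infected, 8.32 ± 1.41% (n = 10) in inulin diet uninfected and 7.35 ± 3.42% (n = 9) in inulin diet infected fish. The difference between the diets had an exact permutation p of 0.0238 in uninfected and 0.04 in infected fish, with an adjusted p of 0.0715 for both. In infected fish the difference of 2.01 points became 0.912 without inulin diet infected library 2, which had a share of 16.1% (exact permutation p = 0.0798, adjusted p = 0.0958), and the adjusted p in uninfected fish then became 0.0477. The TMM scaling factor averaged 1.04, 0.953, 1.09 and 0.945 in the same order, and 6 libraries lay under 0.9. Transcripts of the heart (myl7 above 10 CPM) were found in 9 libraries, 5 of them from uninfected fish, of which 4 were on inulin.

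Infection on the control diet (9 infected against 9 uninfected fish) raised all 44 tested cell cycle genes, with a median log2 fold change of 1.47, and lowered 25 of 27 T cell markers, with a median of −2.28. For these lists camera gave an adjusted p of 3.26e-28 and 1.47e-15 in that order, and adjusted p = 0.0868 and 0.027 with an estimated correlation. The matrix metalloproteinase mmp13a rose from 1.4 ± 1.42 to 244 ± 191 CPM (log2 fold change 7.45 ± 0.74 SE, edgeR adjusted p = 3e-10). The interleukin il1b, an early inflammatory cytokine, rose by 3.02 ± 0.28 on the log2 scale (edgeR adjusted p = 4.68e-11). In all, 4090 of 20199 genes rose and 4499 fell at an edgeR adjusted p under 0.05, and 1775 and 2613 of these changed at least 2-fold.

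Among passing genes with at least 5 CPM and a gene symbol that is not a clone or locus placeholder, the largest increase belonged to teni.1 (ENSDARG00000105096), at 0.395 ± 1.07 CPM in uninfected and 185 ± 138 CPM in infected fish (log2 fold change 8.85 ± 1.19 SE, edgeR adjusted p = 1.94e-07). The chemokine cxl34c rose by 6.93 ± 1.01 and jac2, of the jacalin lectin family, by 6.93 ± 0.76, from 0.494 ± 0.746 to 58.9 ± 51.8 CPM (edgeR adjusted p = 5.9e-07 and 2.14e-09). The cystatin cst14b.2, of a family of cysteine protease inhibitors, rose by 5.22 ± 0.67 (edgeR adjusted p = 6.32e-08). Among the largest decreases, the ammonia transporter rhcga fell from 332 ± 227 to 9.57 ± 10.8 CPM (log2 fold change −5.11 ± 0.56 SE, edgeR adjusted p = 2.58e-09), and the carbonic anhydrase ca15c changed by −5.21 ± 0.66. The NK-lysin nkl.4, an antimicrobial peptide of cytotoxic cells, changed by −5.04 ± 0.80 and il2rb, a chain of the interleukin 2 receptor, by −4.57 ± 0.72 (edgeR adjusted p = 2.6e-06 and 2.69e-06). Of the inflammatory cytokines and mediators, 17 of 38 rose and 8 fell (17 and 8 adjusted over the list alone, camera adjusted p = 0.00468, adjusted p = 0.193 with an estimated correlation).

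The neutrophil chemokines cxcl8a and cxcl18b rose by 3.1 ± 0.27 and 3.06 ± 0.24 (edgeR adjusted p = 1.12e-11 and 7.41e-13). The acute phase protein gene saa rose by 2.43 ± 0.61 (edgeR adjusted p = 0.00129). The cytokines tnfa (−0.20 ± 0.62) and ifng1 (−0.30 ± 0.67) did not pass (edgeR adjusted p = 0.83 and 0.759). The type 2 cytokine il13, which drives mucus and barrier responses in vertebrates, rose from 1.98 ± 2.14 to 20.9 ± 12.5 CPM (log2 fold change 3.4 ± 0.47 SE, edgeR adjusted p = 2.65e-07). The related il4 rose by 1.49 ± 0.61 (edgeR adjusted p = 0.0473). The type 2 list as a whole had 5 members up and 6 down of 16 (camera adjusted p = 0.727). Of the antiviral interferon genes, 19 of 29 rose and none fell (21 and 0 adjusted over the list alone, median 1.26, camera adjusted p = 6.49e-06, adjusted p = 0.29 with an estimated correlation). They included the dynamin-like GTPase mxb at 4.21 ± 0.53 and the ubiquitin-like isg15 at 1.55 ± 0.36 (edgeR adjusted p = 4.22e-08 and 0.000616). Of the class I antigen presentation genes, 12 of 22 rose and 3 fell (camera adjusted p = 0.0376, adjusted p = 0.561 with an estimated correlation).

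Proliferation genes rose together. The mitotic kinase plk1 rose by 1.87 ± 0.15 and the proliferation marker mki67 by 1.62 ± 0.17 (edgeR adjusted p = 3.93e-12 and 1.08e-09). The 44 cell cycle genes also rose when adjusted over the list alone. Among epidermal keratinocyte genes 14 rose and 11 fell of 49 (camera adjusted p = 0.222). Of these tp63, the transcription factor of basal keratinocytes, rose by 2.2 ± 0.15 and the tight junction gene cldnb by 1.36 ± 0.13 (edgeR adjusted p = 4.12e-14 and 2.4e-10). Of the goblet cell and mucus genes, 3 rose and 4 fell of 22 (camera adjusted p = 0.784). The lectin itln1 rose by 3.44 ± 0.45 and agr2, needed for mucin folding, by 1.05 ± 0.29 (edgeR adjusted p = 6.86e-08 and 0.00291).

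Of 26 cholesterol synthesis genes 19 rose and 0 fell (19 and 0 adjusted over the list alone, median 1.18, camera adjusted p = 6.35e-07, adjusted p = 0.265 with an estimated correlation). The gene hmgcs1, an early enzyme of the pathway, rose by 1.93 ± 0.26. Of 33 unfolded protein response genes 18 rose and 2 fell (camera adjusted p = 0.00011, adjusted p = 0.29 with an estimated correlation). The endoplasmic reticulum chaperone hspa5 rose by 1.51 ± 0.19. The mitochondrial chaperonin hspd1 rose by 2.24 ± 0.13. Of 31 heat shock response genes 10 rose and 4 fell (camera adjusted p = 0.00522, adjusted p = 0.29 with an estimated correlation). Of 30 antioxidant genes 14 rose and 3 fell (camera adjusted p = 0.00941, adjusted p = 0.369 with an estimated correlation). The cystine transporter slc7a11 rose by 4.02 ± 0.33 and the peroxiredoxin prdx6 by 1.84 ± 0.17. The edgeR adjusted p of these 5 genes was 1.86e-07 or less. Of 14 aryl hydrocarbon receptor targets 9 fell and 1 rose (camera adjusted p = 0.0125, adjusted p = 0.0766 with an estimated correlation). Of these cyp1a, which oxidises planar xenobiotics, changed by −1.66 ± 0.21 (edgeR adjusted p = 4.37e-08). Of 17 glucocorticoid targets 10 fell and 1 rose (camera adjusted p = 0.0308, adjusted p = 0.426 with an estimated correlation). Of 34 circadian clock genes 15 fell and 3 rose (camera adjusted p = 0.0376, adjusted p = 0.618 with an estimated correlation).

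Of 27 T cell markers 25 fell and none rose (0 up and 26 down adjusted over the list alone, camera adjusted p = 1.47e-15, adjusted p = 0.027 with an estimated correlation). It was the single list of 45 to pass with an estimated correlation. The T cell kinase itk changed by −4.41 ± 0.29, the interleukin 7 receptor il7r by −3.69 ± 0.29 and the coreceptors cd4-1 and cd8a by −3.17 ± 0.35 and −3.99 ± 0.61 (edgeR adjusted p of 1.59e-06 or less for these 4 genes). Among NK and cytotoxic cell markers 16 fell and 1 rose of 22 (median −2.58, camera adjusted p = 9.65e-05, adjusted p = 0.0731 with an estimated correlation), and the median was −1.51 without control diet uninfected library 9. Of 12 type 3 response genes 7 fell and 1 rose (camera adjusted p = 0.0236, adjusted p = 0.29 with an estimated correlation). The interleukin 23 receptor il23r changed by −4.49 ± 0.56 (edgeR adjusted p = 3e-08). The immunoglobulin heavy chain gene ighm changed by −3.08 ± 0.58 (edgeR adjusted p = 4.05e-05), while the B cell list, with 10 of 23 members down and 0 up, did not pass (camera adjusted p = 0.0683).

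Thymus genes, tested because the thymus lies against the gill cavity of fish, fell beside the T cell markers, with 9 of 14 down and 0 up (camera adjusted p = 9.81e-06, adjusted p = 0.0868 with an estimated correlation). Their leading member rag1, which cuts DNA in developing lymphocytes, reached 291 CPM in control diet uninfected library 1 and 52.8 CPM in library 3. Its log2 fold change was −4.76 ± 1.55, with 8 of 9 infected fish below the uninfected mean (edgeR adjusted p = 0.0125). With the mean of rag1 and rag2 as a covariate, the median of the 23 T cell markers outside the thymus list was −2.03 against −2.14 without it. Of 31 macrophage markers 13 fell and 3 rose (camera adjusted p = 0.0295, adjusted p = 0.566 with an estimated correlation). The pore-forming mpeg1.1 changed by −1.47 ± 0.20 (edgeR adjusted p = 1.18e-07). Class II presentation had 5 of 15 genes down and 1 up (camera adjusted p = 0.0391, adjusted p = 0.426 with an estimated correlation). The invariant chain gene cd74a changed by −1.54 ± 0.22 (edgeR adjusted p = 4.83e-07). Neutrophil markers went both ways, 9 up and 6 down of 26 (camera adjusted p = 0.26). The gelatinase mmp9 stood at 2.24 ± 0.30 and the myeloperoxidase mpx at −1.16 ± 0.26 (edgeR adjusted p = 1.56e-07 and 0.000351).

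Of 37 markers of ionocytes, the cells that transport salt and acid across the gill, 24 fell and 2 rose (26 and 2 adjusted over the list alone, median −1.15, camera adjusted p = 9.81e-06, adjusted p = 0.265 with an estimated correlation). The ionocyte transcription factors foxi3b and foxi3a changed by −1.91 ± 0.19 and −1.15 ± 0.22 (edgeR adjusted p = 3.72e-10 and 4.14e-05). Extracellular matrix genes had 17 down and 2 up of 34 and endothelial markers 13 down and 1 up of 26. The camera adjusted p was 0.00255 and 0.0236 in that order, and adjusted p = 0.566 and 0.566 with an estimated correlation. The vascular transcription factor fli1 changed by −0.89 ± 0.15 (edgeR adjusted p = 6.61e-06). Markers of tissues next to the gill fell as well, 26 of 37 skeletal muscle genes, 19 of 34 cartilage and bone genes and 15 of 25 neural genes. For these 3 lists the camera adjusted p was 6.49e-06, 0.000596 and 0.00522 in that order, and adjusted p = 0.426, 0.426 and 0.426 with an estimated correlation. The muscle gene mybpc1 changed by −1.59 ± 0.21 (edgeR adjusted p = 6.66e-08). Dendritic cell markers (7 of 17 down) and mast cell and eosinophil markers (4 of 10 down) completed the 25 passing lists. Their camera adjusted p was 0.0376 and 0.0459 in that order, and adjusted p = 0.29 and 0.236 with an estimated correlation.

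Every infected fish lay beyond the mean of the uninfected fish for 43 of the 44 passing genes named, the exception being rag1. The count of passing genes was 8564 with library round as a covariate, and the second round held only 3 uninfected and 2 infected control diet libraries, too few for a value of its own. With the estimated correlation 1 of 25 list calls held, and with fry 30 lists passed. Without control diet uninfected library 9, which had 19283 genes detected, the macrophage, class II and endothelial lists did not pass (camera adjusted p = 0.0646, 0.0842 and 0.05), nor did class II without inulin diet infected library 2 (camera adjusted p = 0.0555). The il4 call ended without the filter on low counts and without 6 libraries listed out of number order, and the rag1 call in the latter and in a limma voom fit.

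**Figure D1:**
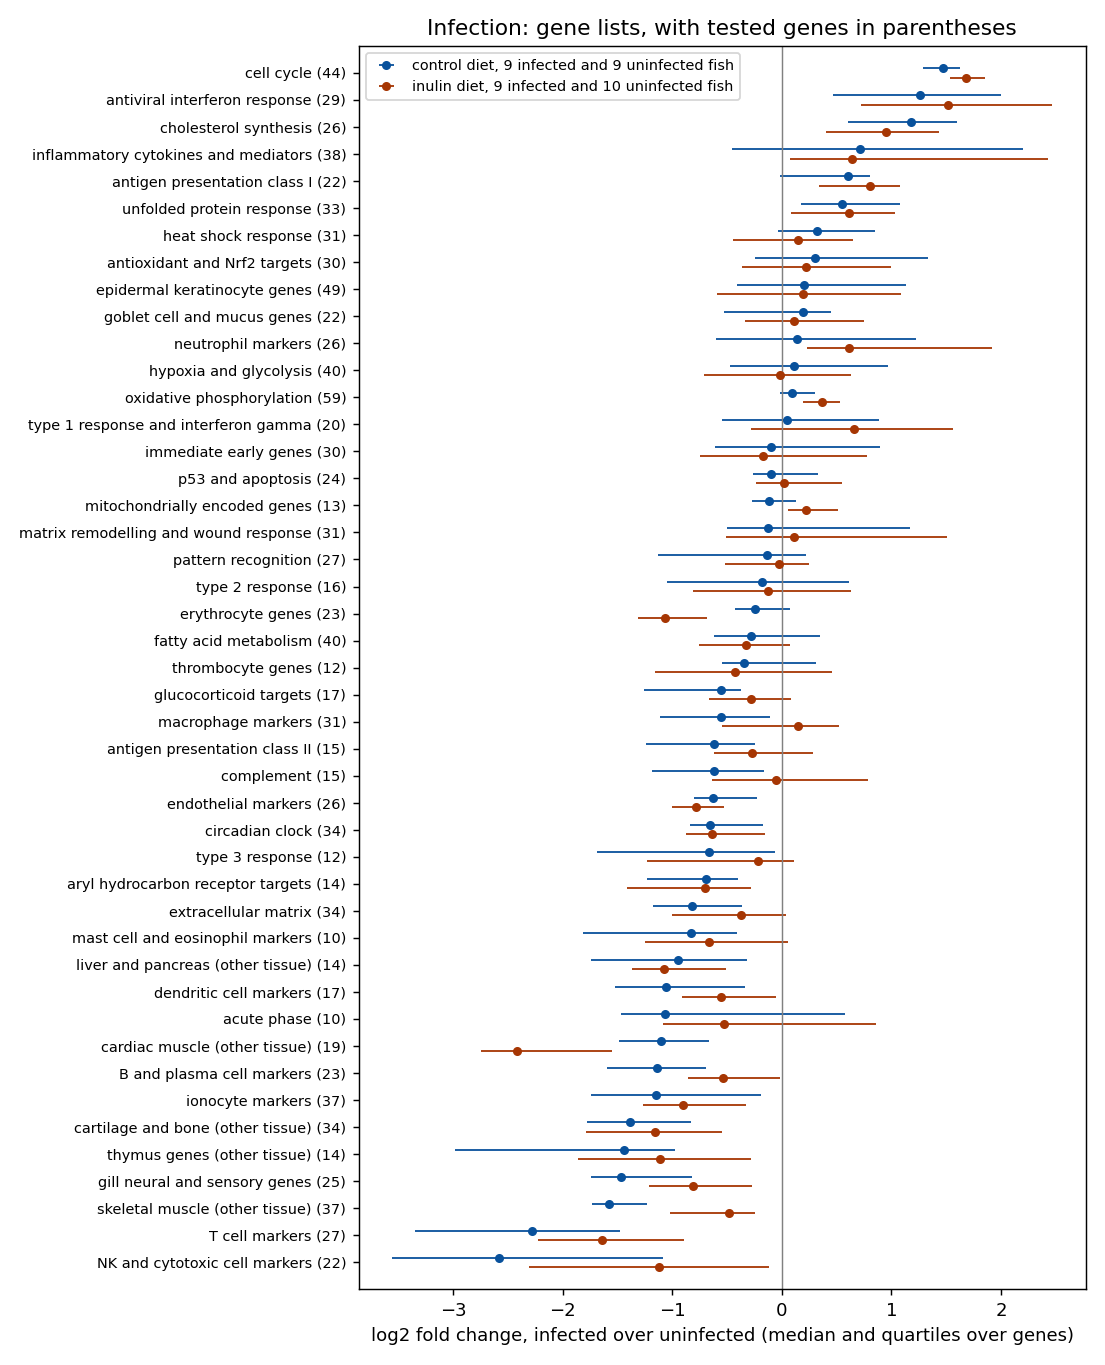
Median log2 fold change of gene lists with infection, with quartiles over the tested members as bars, on the control diet (9 infected against 9 uninfected fish) and on the inulin diet (9 against 10). Cell cycle genes have medians of 1.47 and 1.68 and T cell markers medians of −2.28 and −1.64.

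**Figure D2:**
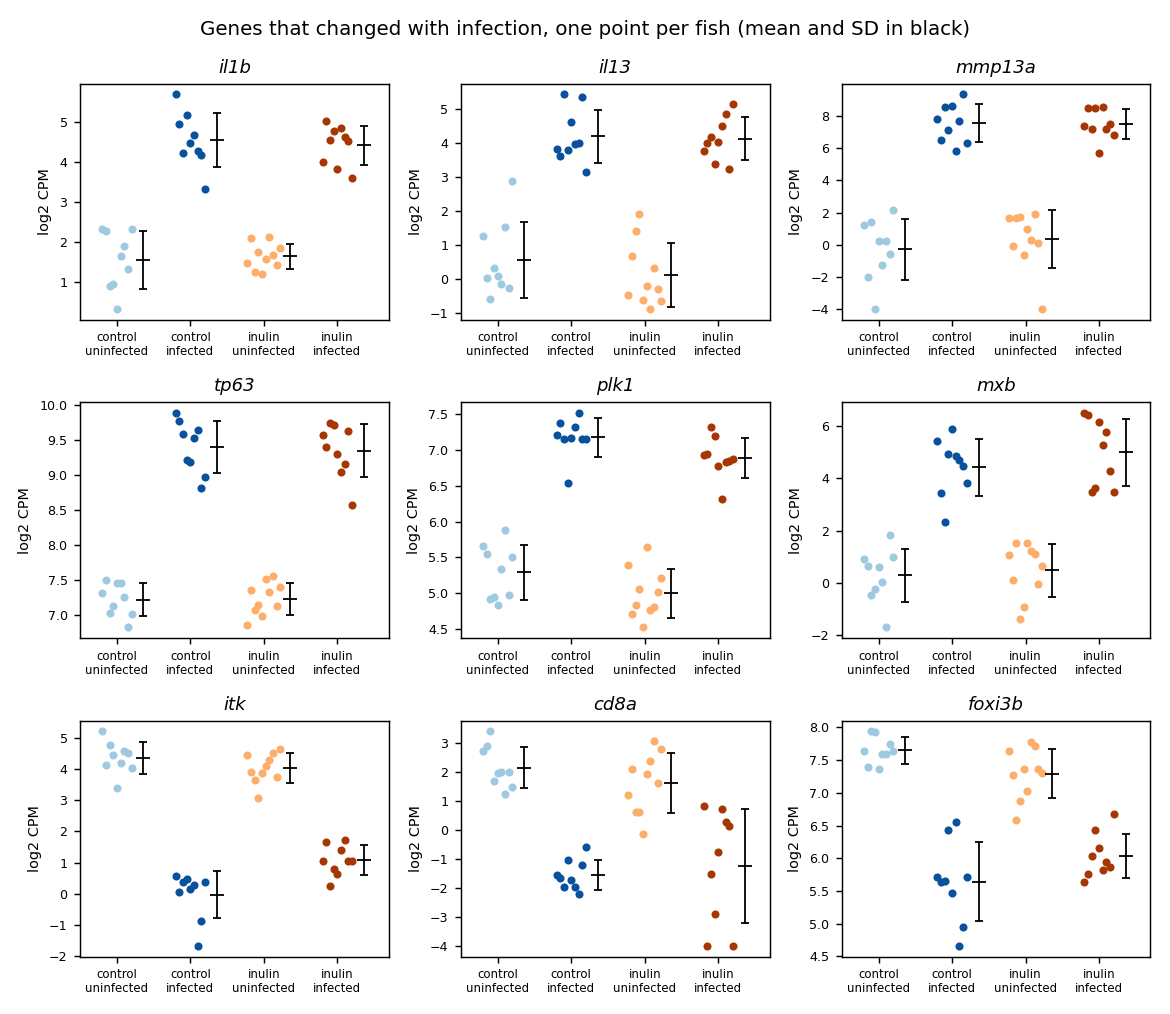
Log2 CPM of 9 genes in each of the 37 libraries by group, with group means and SD. For il1b, il13, mmp13a, tp63, plk1 and mxb the infected fish of both diets lie above the uninfected means, and for itk, cd8a and foxi3b below them.

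Infection on the inulin diet (9 infected against 10 uninfected fish) raised all 44 cell cycle genes, also adjusted over the list alone, with a median log2 fold change of 1.68 (camera adjusted p = 1.21e-42, adjusted p = 0.0303 with an estimated correlation). Of 27 T cell markers 22 fell and 1 rose (23 and 1 adjusted over the list alone, median −1.64, camera adjusted p = 1.3e-09, adjusted p = 0.0615 with an estimated correlation). The cystatin cst14b.2 rose from 0.322 ± 0.451 to 130 ± 104 CPM (log2 fold change 8.63 ± 0.76 SE, edgeR adjusted p = 2.73e-11), and mmp13a from 1.86 ± 1.31 to 210 ± 120 CPM (6.82 ± 0.69, edgeR adjusted p = 5.44e-10). In all, 4234 genes rose and 3634 fell at an edgeR adjusted p under 0.05, of which 1759 and 1787 changed at least 2-fold. More genes fell than rose with median-ratio scaling (3997 rose, 4080 fell), in DESeq2 (4170 and 4606) and without 6 libraries of low TMM factor (4521 and 4793).

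Among the largest increases were jac2 (8.13 ± 0.78), the microfibril-associated family member mfap4.9 (7.19 ± 0.92), teni.1 (7.79 ± 1.07) and the Kazal-type protease inhibitor spink2.10 (6.91 ± 0.74), with an edgeR adjusted p of 3.24e-07 or less. Of 38 inflammatory genes 18 rose and 2 fell (18 and 3 adjusted over the list alone, median 0.64, camera adjusted p = 4.51e-06, adjusted p = 0.0303 with an estimated correlation). Cell cycle and inflammatory genes were the 2 lists that passed with an estimated correlation. The cytokine il1b rose by 2.84 ± 0.27, cxcl8a by 2.89 ± 0.26 and cxcl18b by 3.22 ± 0.23 (edgeR adjusted p of 1.08e-10 or less). The acute phase gene saa rose by 4.44 ± 0.63, il13 by 3.87 ± 0.46 and il4 by 1.91 ± 0.60 (edgeR adjusted p = 5.33e-07, 1.82e-08 and 0.0111). The cytokines tnfa (0.65 ± 0.61) and ifng1 (−0.08 ± 0.66) did not pass (edgeR adjusted p = 0.421 and 0.934). Of 29 antiviral interferon genes 24 rose and 0 fell (25 and 0 adjusted over the list alone, camera adjusted p = 1.85e-09, adjusted p = 0.189 with an estimated correlation). The gene mxb rose by 4.75 ± 0.52, isg15 by 2.79 ± 0.36 and the interferon-activated transcription factor stat1b by 2.34 ± 0.22 (edgeR adjusted p of 9.79e-08 or less). Class I presentation genes had 14 up and 2 down of 22 (camera adjusted p = 0.000328, adjusted p = 0.298 with an estimated correlation).

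Neutrophil markers had 12 members up and 2 down of 26 (14 and 3 adjusted over the list alone, camera adjusted p = 0.000551, adjusted p = 0.298 with an estimated correlation). The gelatinase mmp9 rose by 2.85 ± 0.30, and mpx stood at −0.60 ± 0.25 and did not pass (edgeR adjusted p = 1.04e-09 and 0.0539). The macrophage list did not pass (8 up, 6 down of 31, camera adjusted p = 0.495), though mpeg1.1 fell (log2 fold change −0.79 ± 0.19 SE, edgeR adjusted p = 0.000968). Cholesterol synthesis rose in 18 of 26 genes with 0 down (median 0.95, camera adjusted p = 4.61e-06, adjusted p = 0.298 with an estimated correlation), and hmgcs1 rose by 1.67 ± 0.25. The unfolded protein response had 21 genes up and 2 down of 33 (camera adjusted p = 3.39e-05, adjusted p = 0.298 with an estimated correlation), with hspa5 up by 1.5 ± 0.19, and hspd1 rose by 1.64 ± 0.12. Antioxidant genes had 12 up and 6 down of 30 and oxidative phosphorylation genes 18 up and 2 down of 59. Camera gave these lists an adjusted p of 0.0187 and 0.0233 in that order, and adjusted p = 0.494 and 0.84 with an estimated correlation. Without inulin diet infected library 2 the latter list did not pass (camera adjusted p = 0.223). The peroxiredoxin prdx6 rose by 2.22 ± 0.17. The epithelial genes tp63 and cldnb rose by 2.14 ± 0.15 and 1.19 ± 0.13, itln1 by 5.23 ± 0.46 and agr2 by 1.88 ± 0.28. The mitotic kinase plk1 rose by 1.88 ± 0.15 and mki67 by 1.57 ± 0.17. The edgeR adjusted p of these 10 genes was 1.37e-06 or less. The keratinocyte list had 20 up and 11 down of 49 and did not pass (camera adjusted p = 0.0574).

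Among the genes that fell, itk changed by −2.99 ± 0.26, il7r by −2.88 ± 0.28, il2rb by −4.32 ± 0.70 and il23r by −3.48 ± 0.53 (edgeR adjusted p of 5.21e-06 or less). The coreceptors cd4-1 and cd8a changed by −1.43 ± 0.32 and −2.37 ± 0.56 (edgeR adjusted p = 0.000481 and 0.000798), and ighm at −0.92 ± 0.53 did not pass (edgeR adjusted p = 0.177). NK and cytotoxic markers had 10 down and 1 up of 22 and thymus genes 9 down and 0 up of 14. They had a camera adjusted p of 0.0134 and 0.000308 in that order, and adjusted p = 0.298 and 0.192 with an estimated correlation. Ionocyte markers had 20 down and 1 up of 37 (22 and 1 adjusted over the list alone, camera adjusted p = 4.16e-05, adjusted p = 0.298 with an estimated correlation). The ionocyte gene foxi3b stood at −1.27 ± 0.19, foxi3a at −0.99 ± 0.21 and rhcga at −2.67 ± 0.50 (edgeR adjusted p of 0.000269 or less). Endothelial markers had 18 down and 1 up of 26 (camera adjusted p = 0.000294, adjusted p = 0.429 with an estimated correlation). Aryl hydrocarbon receptor targets had 9 down and 1 up of 14 and clock genes 16 down and 1 up of 34. Here the camera adjusted p was 0.0141 and 0.000463 in that order, and adjusted p = 0.0889 and 0.494 with an estimated correlation. The endothelial fli1 stood at −1.13 ± 0.15 and cyp1a at −1.59 ± 0.21 (edgeR adjusted p = 9.3e-08 and 9.78e-08). The largest decreases included crispld1b at −4.65 ± 0.51 and pck1, a key enzyme of gluconeogenesis, at −3.65 ± 0.58 (edgeR adjusted p = 3.4e-09 and 3.36e-06).

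Erythrocyte genes had 14 members down and 1 up of 23, cartilage and bone genes 20 down and 1 up of 34, and extracellular matrix genes 13 down and 1 up of 34. Their adjusted p by camera was 0.00882, 0.00145 and 0.0281 in that order, and adjusted p = 0.641, 0.548 and 0.724 with an estimated correlation. Skeletal muscle genes had 11 down and 1 up of 37 and did not pass (camera adjusted p = 0.0693). The iron hormone gene hamp passed on neither diet, at 0.93 ± 0.86 on control diet and 0.76 ± 0.82 on inulin (edgeR adjusted p = 0.412 and 0.492). Every infected fish lay beyond the mean of the uninfected fish for all 40 passing genes named. The count was 7937 genes with library round as a covariate, and the second round held only 1 inulin library in each infection state. With the estimated correlation 2 of 19 list calls held, and with fry 28 lists passed.

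The effects of infection on the 2 diets, which share no library, were correlated across 20199 genes, which are not independent replicates (Pearson r = 0.798, Spearman rho = 0.823). Of the passing genes, 6216 passed on both diets and 6212 of these had the same direction. For independent lists of these sizes 857.3 genes would rise in both and 809.4 would fall in both, against 3391 and 2821 observed. The slope of inulin on control diet effects was 0.733, which noise in the latter lowers. The ratio of their median absolute values, inulin over control diet, was 0.879 over genes called in the averaged contrast. Averaged over the diets, 5207 genes rose and 5926 fell (edgeR adjusted p under 0.05), and 20 lists passed. Among these, all 44 cell cycle genes and 25 of 29 antiviral genes rose, and 26 of 27 T cell markers fell and 1 rose. The adjusted p by camera was 2.17e-36, 9.27e-08 and 2.82e-13 in that order, and adjusted p = 0.0505, 0.26 and 0.0505 with an estimated correlation. Inflammatory genes had 20 up and 8 down of 38, cholesterol synthesis 20 up of 26 and ionocyte markers 26 down and 2 up of 37. Camera adjusted p values were 0.000147, 7.69e-07 and 1.42e-05 in that order, and adjusted p = 0.0505, 0.262 and 0.262 with an estimated correlation.

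**Figure D3:**
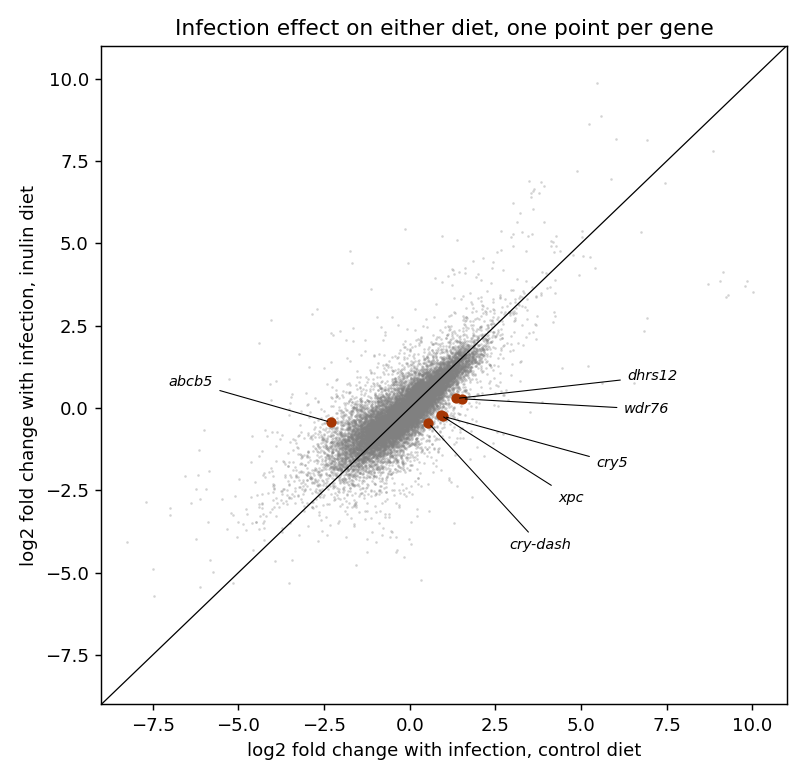
Log2 fold change with infection on the inulin diet against that on the control diet for the 20199 tested genes, 1 point per gene, with the line of equal effects and the 6 genes that passed the interaction test in red. The gene abcb5 lies above the line and the other 5 red genes below it.

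Inulin in uninfected fish (10 inulin against 9 control diet fish) changed 104 genes, among them 9 of 34 circadian clock genes that went both ways. The clock repressor ciarta fell from 61 ± 15.6 to 16.8 ± 3.94 CPM (log2 fold change −1.86 ± 0.21 SE, edgeR adjusted p = 3.84e-06), and the period gene per1a changed by −1.66 ± 0.31 (edgeR adjusted p = 0.00552). The cryptochromes cry3a and cry3b rose by 1.37 ± 0.18 and 1.69 ± 0.22, and the related DNA photolyase cry5 by 1.17 ± 0.16 (edgeR adjusted p = 4.07e-05, 2.27e-05 and 8.17e-05). In CPM, cry3a went from 90 ± 17.9 to 233 ± 39.6. The clock activators arntl1a and arntl2 rose by 0.61 ± 0.11 and 1.16 ± 0.28 (edgeR adjusted p = 0.00334 and 0.04). In all, 38 genes rose and 66 fell at an edgeR adjusted p under 0.05, 104 of 20199, of which 19 and 27 changed at least 2-fold.

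Of 34 clock genes 4 rose and 5 fell (6 and 10 adjusted over the list alone), and the list, whose members went both ways, did not pass as a whole (camera adjusted p = 0.41). Other genes that rose were the dehydrogenase dhrs12 (1.14 ± 0.14), prxl2b (1.05 ± 0.18), the lipid transporter abca7 (1.03 ± 0.23), the blood group gene kel (2.01 ± 0.45), the histone deacetylase hdac4 (2.31 ± 0.54) and grhl3, a transcription factor of the epidermal barrier (0.73 ± 0.14), with an edgeR adjusted p of 0.0337 or less. The transporter gene abcb5 fell from 264 ± 88.3 to 76.2 ± 19.2 CPM (−1.79 ± 0.26, edgeR adjusted p = 0.000165) and rhcga from 332 ± 227 to 66.6 ± 22.3 CPM (−2.32 ± 0.48, edgeR adjusted p = 0.0126). The deubiquitinase cyldb changed by −1.89 ± 0.33 and the growth arrest gene gadd45ab by −1.05 ± 0.19 (edgeR adjusted p = 0.00275 and 0.00474).

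Glucocorticoid targets had 3 members down and 0 up of 17 (0 up and 7 down adjusted over the list alone, median −0.68, camera adjusted p = 1.41e-05, adjusted p = 0.132 with an estimated correlation). They were tsc22d3 (−1.47 ± 0.34), which binds inflammatory transcription factors, the phosphatase gene dusp1 (−0.82 ± 0.20) and the transcription factor cebpd (−1.3 ± 0.30), with an edgeR adjusted p of 0.0308, 0.0473 and 0.0331. The cytokine feedback gene socs3a (−1.51 ± 0.33), the chemokine ccl19b (−1.52 ± 0.31), the cyclooxygenase ptgs2a (−0.74 ± 0.18), the survival gene mcl1b (−0.66 ± 0.14), myca (−0.64 ± 0.15) and the lysosomal protease lgmn (−0.47 ± 0.11) also fell (edgeR adjusted p of 0.0473 or less). The immunoglobulin heavy chain gene ighm changed by −2.33 ± 0.54 and the lysozyme gene lyz by −2.1 ± 0.49 (edgeR adjusted p = 0.0324 and 0.0337). For lyz, control diet uninfected library 9 stood at 6.59 log2 CPM against 3.3 to 4.81 in the other 8. Without it ighm was at −1.65 and lyz at −1.55, and neither passed (edgeR adjusted p = 0.166 and 0.16). The replication helicase genes mcm2 and mcm4 changed by −0.85 ± 0.19 and −0.79 ± 0.17 (edgeR adjusted p = 0.0208 and 0.0199). In all 2 of 44 cell cycle genes fell and 0 rose (0 up and 18 down adjusted over the list alone, median −0.40, camera adjusted p = 1.09e-19, adjusted p = 0.155 with an estimated correlation).

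Immune cell lists lay lower on inulin with few single genes past the threshold. Macrophage markers had 1 of 31 down (0 up and 13 down adjusted over the list alone, median −0.49, camera adjusted p = 1.36e-13, adjusted p = 0.132 with an estimated correlation). NK and cytotoxic markers had 1 of 22 down (median −0.66), class II presentation 1 of 15, B and plasma cell markers 1 of 23 and neutrophil markers 1 of 26. These 4 lists had a camera adjusted p of 0.000895, 4.39e-05, 0.00369 and 5.06e-05 in that order, and adjusted p = 0.132, 0.132, 0.132 and 0.155 with an estimated correlation. T cell markers had 0 of 27 past the edgeR threshold (1 down adjusted over the list alone, median −0.36), and inflammatory genes 3 of 38 down (median −0.27). For both lists camera passed, with an adjusted p of 5.94e-05 and 0.00286 in that order, and adjusted p = 0.184 and 0.155 with an estimated correlation. Complement (median −0.49), class I presentation (−0.27), thymus genes (−0.36) and type 1 response genes (−0.32) were also lower. Here camera gave an adjusted p of 0.00438, 0.00208, 0.00875 and 0.026 in that order, and adjusted p = 0.183, 0.37, 0.345 and 0.432 with an estimated correlation. The perforin prf1.7, a pore-forming protein of cytotoxic cells, changed by −3.41 ± 0.83 (edgeR adjusted p = 0.0459). This rested on control diet uninfected library 9 at 5.99 log2 CPM, against −0.40 to 0.78 in the other 8. Without it the change was −0.48 (edgeR adjusted p = 0.973).

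Lists that were higher on inulin included erythrocyte genes (median 0.28), cholesterol synthesis (0.26) and mitochondrially encoded genes (0.34). By camera their adjusted p was 5.11e-06, 0.000337 and 0.000337 in that order, and adjusted p = 0.255, 0.388 and 0.445 with an estimated correlation. Hypoxia and glycolysis (0.17), keratinocyte genes (0.12), endothelial markers (0.14) and cardiac muscle genes (1.53) were higher too, and the heart transcript myl7 exceeded 10 CPM in 4 inulin libraries and 1 control diet library. They had an adjusted p by camera of 0.000533, 0.00429, 0.0187 and 0.00372 in that order, and adjusted p = 0.325, 0.435, 0.563 and 0.563 with an estimated correlation. Ionocyte markers (−0.11) and oxidative phosphorylation genes (−0.16) lay lower. Both passed camera, at an adjusted p of 0.0366 and 0.00842 in that order, and adjusted p = 0.563 and 0.78 with an estimated correlation. Without control diet uninfected library 9 the median of erythrocyte genes was 0.81, of endothelial markers 0.23, of class I presentation −0.18 and of type 1 response genes −0.19. There oxidative phosphorylation did not pass (camera adjusted p = 0.251) and the clock list did (median −0.24, camera adjusted p = 0.0253). Of these 22 passing lists 0 passed with an estimated correlation and 10 with fry. Among the 18 genes named whatever their result, ighm alone passed, the others ranging up to 0.61 with an edgeR adjusted p of 0.207 or more.

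Every inulin fish lay beyond the mean of the control diet fish for 25 of the 31 passing genes named, and 9 of 10 did for the other 6. Within the first library round (6 control and 9 inulin diet fish) 52 genes passed. There 7 of the 9 clock genes that had passed in all fish passed, with a median change in their direction of 0.98 against 1.17, and the second round held 1 inulin fish. With round as a covariate 56 genes passed, all among the 104. The count was 29 (20 higher, 9 lower) without 6 libraries listed out of number order, 21 (14 higher, 7 lower) without the libraries with heart transcripts and 907 (365 higher, 542 lower) without 6 libraries of low TMM factor, with 28, 21 and 98 of the 104 among these. Without control diet uninfected library 9 it was 64 (25 higher, 39 lower), 62 of them among the 104, and of the genes named arntl2, prf1.7, ighm, lyz, mcm2, dusp1, kel, hdac4, abca7 and lgmn did not pass. The genes ciarta, cry3a, cry3b, cry5, arntl1a, dhrs12, abcb5 and prxl2b passed in every setting.

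**Figure D4:**
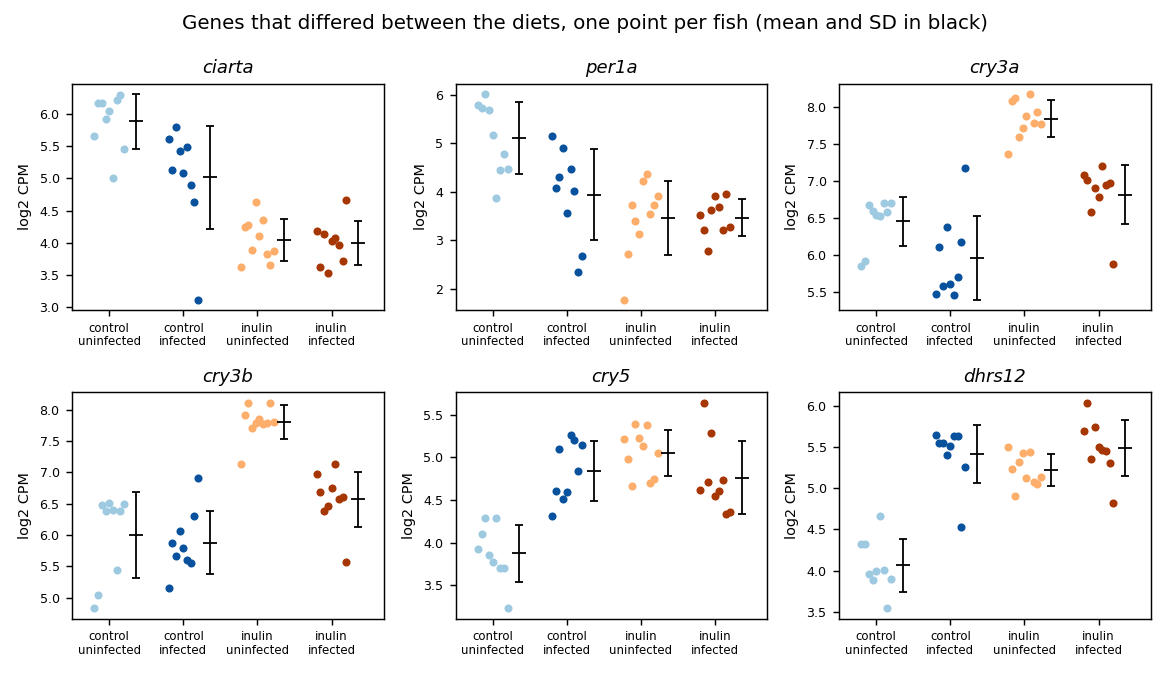
Log2 CPM of ciarta, per1a, cry3a, cry3b, cry5 and dhrs12 in each of the 37 libraries by group, with group means and SD. In uninfected fish all 10 inulin libraries lie below the control diet mean for ciarta and per1a and above it for the other 4 genes.

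Inulin in infected fish (9 against 9) changed 4 genes, 1 higher and 3 lower (edgeR adjusted p under 0.05, with 1987 genes at an unadjusted p under 0.05). The chemokine ccl25a, which attracts developing T cells to the thymus, was at 18.1 ± 8.96 CPM on control diet and 47.6 ± 17.4 CPM on inulin (log2 fold change 1.39 ± 0.26 SE, edgeR adjusted p = 0.0324). The heat shock transcription factor hsf2 changed by −0.67 ± 0.12, the ribosome assembly gene rrp12 by −0.60 ± 0.11 and ciarta by −1.14 ± 0.22 (edgeR adjusted p = 0.0324, 0.0324 and 0.0328). The RNA helicase ddx18, next in rank, did not pass (−0.61 ± 0.12, edgeR adjusted p = 0.0544). All 9 inulin fish lay beyond the control diet mean for each of the 4 genes.

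Of 45 lists 12 passed. Clock genes had 1 of 34 down and 0 up (2 up and 11 down adjusted over the list alone, median −0.21, camera adjusted p = 7.28e-05, adjusted p = 0.495 with an estimated correlation). Cell cycle genes had 0 of 44 past the edgeR threshold (0 also adjusted over the list alone, median −0.22) and heat shock genes 1 of 31 down (median −0.17). Both lists passed camera, at an adjusted p of 7.26e-07 and 0.000546 in that order, and adjusted p = 0.595 and 0.416 with an estimated correlation. Goblet cell and mucus genes (median 0.37), keratinocyte genes (0.24), T cell markers (0.34), complement (0.29) and extracellular matrix genes (0.17) were higher on inulin. These 5 lists passed camera at an adjusted p of 0.000125, 1.2e-05, 0.000248, 0.0477 and 0.0477 in that order, and adjusted p = 0.41, 0.416, 0.447, 0.495 and 0.81 with an estimated correlation. So were skeletal muscle (0.70), neural (0.74) and mitochondrially encoded genes (0.63, with 11 of 13 higher adjusted over the list alone), while erythrocyte genes were lower (−0.21). Their camera p values, adjusted, were 1.21e-14, 6.2e-08, 1.49e-06 and 0.0439 in that order, and adjusted p = 0.41, 0.41, 0.495 and 0.758 with an estimated correlation. None of these calls held with an estimated correlation, and fry called 0 lists. None of the 18 genes named whatever their result passed (log2 fold changes −0.62 to 1.53, edgeR adjusted p of 0.161 or more).

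Without inulin diet infected library 2, which had 16272 genes detected and a mitochondrial share of 16.1%, edgeR called 0 genes (1731 at an unadjusted p under 0.05), and without the libraries with heart transcripts 0 genes (1709). DESeq2 called 203 genes and limma voom 1040 over all libraries, and without the 6 libraries of low TMM factor edgeR called 771, 66 higher and 705 lower. With library round as a covariate 4 genes passed. Without library 2 the median of mitochondrially encoded genes was 0.23, with 0 of 13 higher adjusted over the list alone (camera adjusted p = 0.0269). Complement (0.11), extracellular matrix (0.09) and erythrocyte genes (−0.12) then did not pass (camera adjusted p = 0.475, 0.799 and 0.0547), and oxidative phosphorylation (−0.06) and antioxidant genes (−0.05) did (camera adjusted p = 0.000527 and 0.0396).

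Averaged over infection states, inulin raised 27 genes and lowered 49 (edgeR adjusted p under 0.05). Clock genes had 4 of 34 up and 7 down (6 and 12 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.721 with an estimated correlation), with ciarta at −1.5 ± 0.15 (edgeR adjusted p = 1.56e-07). Cell cycle genes had 2 of 44 down over all genes and 24 down adjusted over the list alone (median −0.30, camera adjusted p = 1.73e-21, adjusted p = 0.385 with an estimated correlation). Mitochondrially encoded genes had 11 of 13 higher adjusted over the list alone (median 0.47), and keratinocyte genes 12 of 49 (median 0.26). Camera gave an adjusted p of 1.72e-08 and 1.5e-06 in that order, and adjusted p = 0.385 and 0.385 with an estimated correlation. Without inulin diet infected library 2 the median of mitochondrially encoded genes was 0.29, with 0 of 13 higher adjusted over the list alone (camera adjusted p = 3.74e-05), and keratinocyte genes had 8 of 49 higher (median 0.20). In all 12 lists passed, 0 of them with an estimated correlation and 0 with fry, and 35 genes passed with library round as a covariate.

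The interaction asks whether infection acted differently on the 2 diets, and 6 genes passed (edgeR adjusted p under 0.05, with 1599 at an unadjusted p under 0.05). The cryptochrome cry-dash, of a family of light-driven DNA repair enzymes, went from an infection effect of 0.54 on control diet to −0.46 on inulin (difference −1.0 ± 0.14 SE, edgeR adjusted p = 0.000308). The photolyase cry5 went from 0.97 on control diet to −0.25 on inulin (difference −1.22 ± 0.23, edgeR adjusted p = 0.0328). The gene xpc, which recognises DNA damage for excision repair, went from 0.90 on control diet to −0.21 on inulin (difference −1.12 ± 0.21, edgeR adjusted p = 0.0328). For dhrs12 the effect went from 1.35 on control diet to 0.29 on inulin (difference −1.06 ± 0.20, edgeR adjusted p = 0.0328). For wdr76 it went from 1.52 on control diet to 0.28 on inulin (difference −1.23 ± 0.24, edgeR adjusted p = 0.0377). The transporter abcb5 fell from 264 ± 88.3 to 53.5 ± 31.1 CPM on control diet and was at 76.2 ± 19.2 and 56.4 ± 25.8 CPM on inulin (difference 1.87 ± 0.37, edgeR adjusted p = 0.0474).

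Of 45 lists 25 differed in their response to infection, 19 of them with a more positive effect on inulin. Macrophage markers (0.68), T cell markers (0.63), NK and cytotoxic markers (0.97) and complement (1.08) had positive median differences. Of their members 13, 9, 0 and 6 were higher adjusted over the list alone, and 0 over all genes. For these 4 the camera adjusted p was 2.95e-12, 1.87e-09, 3.57e-05 and 0.000106 in that order, and adjusted p = 0.0671, 0.0671, 0.0671 and 0.0671 with an estimated correlation. Skeletal muscle genes (0.86) also had a positive median and erythrocyte genes (−0.92) a negative one. These had a camera adjusted p of 2.21e-11 and 7e-08 in that order, and adjusted p = 0.198 and 0.181 with an estimated correlation. None of the 25 calls held with an estimated correlation, and fry called 7. None of the 6 genes passed without the libraries with heart transcripts, where 3 other genes did, and 9 genes passed with library round as a covariate. Without inulin diet infected library 2 complement had a median of 0.91 with 0 members higher adjusted over the list alone. Without control diet uninfected library 9 the median of NK and cytotoxic markers was 0.51, and abcb5 did not pass (1.89, edgeR adjusted p = 0.0532).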

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

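Tests chosen only after the result was seen were the fits without single libraries, the fit of the clock genes without libraries of low TMM factor, the comparison of T cell markers with 4 other cell lists, and the TMM factor as a covariate for the ribosomal protein genes. The ribosomal protein genes themselves were chosen after their values were seen.

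A library far from the others of its group appeared in 3 of 24 groups of library quality values, where chance gives about 1 in 20. Control diet uninfected library 9 had 19283 genes detected, against 20942 to 21814 in the other 8. Inulin diet infected library 2 had 16272 genes detected, against 19268 to 21804 in the others. Its mitochondrial share of counts was 16.1%, against 5.11% to 7.76%.

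Among the named genes, 20 of 270 groups of log2 CPM values held a library far from the others, where chance gives about 1 in 20. A value of −3.98 is that of a count of 0. In control diet uninfected fish, library 9 stood apart for prf1.7 (5.99, others −0.40 to 0.78), lyz (6.59, others 3.3 to 4.81) and abca7 (1.44, others 2.18 to 2.73). Library 1 did for teni.1 (1.73, others −3.98 to −2.0), library 2 for tnfa (−3.98, others −1.8 to −0.29), library 7 for hmgcs1 (5.34, others 3.84 to 4.41) and library 5 for cyp1a (8.28, others 6.61 to 7.41). In control diet infected fish, library 8 stood apart for il2rb (−3.98, others −1.19 to 0.27) and dhrs12 (4.53, others 5.26 to 5.65). Library 4 did for plk1 (6.54, others 7.15 to 7.52) and library 9 for ciarta (3.12, others 4.63 to 5.79).

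In inulin diet uninfected fish, library 1 stood apart for hspa5 (8.39, others 6.72 to 7.48) and cry3b (7.13, others 7.7 to 8.11), and library 3 for mpeg1.1 (4.93, others 6.02 to 7.06). Library 4 did for teni.1 (3.28, others −3.98 to −0.24) and mcl1b (6.42, others 6.95 to 7.54). Library 5 did for prf1.7 (−3.98, others −1.02 to 1.03) and socs3a (7.59, others 5.54 to 6.56), and library 10 for mmp13a (−3.98, others −0.66 to 1.88). In inulin diet infected fish, library 2 stood apart for cxcl18b (10.15, others 8.26 to 8.85).

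The effect of infection differed between the diets, by the edgeR interaction test, for 6 genes. The log2 difference was −1.0 for cry-dash, −1.06 for dhrs12, −1.22 for cry5, −1.12 for xpc, −1.23 for wdr76 and 1.87 for abcb5 (edgeR adjusted p of 0.0474 or less), of which abcb5 did not pass without control diet uninfected library 9 (1.89, edgeR adjusted p = 0.0532). At least as many genes came from 2 of 100 splits of the libraries, with 6 genes in the real split and 12 in the highest other. Splits also broke up the effect of diet or infection, so they cannot exclude chance for the interaction.

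Of the gene lists, 25 differed between the diets in their median effect of infection by camera. The positive median differences among markers of immune cells were 0.68 for macrophage, 0.63 for T cell, 0.46 for neutrophil, 0.97 for NK and cytotoxic, 0.56 for B and plasma, 0.45 for dendritic and 0.45 for mast cell and eosinophil genes. Among immune pathways they were 1.08 for complement, 0.59 for class II and 0.30 for class I presentation, 0.44 for type 1, 0.32 for type 3 and 0.40 for inflammatory genes. Other positive median differences were 0.86 for skeletal muscle, 0.48 for neural, 0.38 for thymus, 0.18 for cell cycle, 0.46 for glucocorticoid target and 0.34 for extracellular matrix genes. The negative ones were −0.92 for erythrocyte, −0.19 for heat shock, −0.21 for hypoxia and glycolysis, −0.13 for clock, −0.15 for endothelial and −0.26 for cholesterol synthesis genes. The camera adjusted p ran from 2.95e-12 for macrophage markers to 0.0456 for mast cell markers, and with an estimated correlation the lowest adjusted p = 0.0671. Without inulin diet infected library 2 mast cell and extracellular matrix genes did not pass (camera adjusted p = 0.0709 and 0.289), and the medians of clock and endothelial genes were −0.00 and −0.06. Without control diet uninfected library 9 cell cycle, clock and extracellular matrix genes did not pass (camera adjusted p = 0.0604, 0.112 and 0.145), and the medians of NK and endothelial markers were 0.51 and −0.23. The count of 25 lists was reached by 1 of 100 splits, and another split gave 24 lists. Since splits broke up other effects too, chance is not excluded for that count or any single list.

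Clock genes differed between the diets in uninfected fish, by a median of 1.17 on the log2 scale over the 9 that passed, each taken in its own direction. The tables argue against library round as the whole source, since the median was 0.98 over the 30 libraries of the first round, and against libraries of low TMM factor, since it was 1.25 without them. Another hour of sampling stays open: across 34 clock genes, which are not independent, the diet difference had a correlation of 0.12 with the main axis on which fish of one group differed, and the hour is not in the labels. Genes of the bmal, clock and npas2 families had a median of 0.75 (6 of 6 above 0) and per, nr1d, ciart and dbp genes a median of −0.69 (11 of 13 below 0), opposite directions such as a shift of phase might give. An effect of the diet itself on the clock also stays open and was not tested apart from the hour.

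T cell and NK markers were lower in infected gills, with medians of −2.28 and −2.58 on control diet, the latter −1.51 without control diet uninfected library 9. The tables argue against thymus tissue in some samples as the whole source, since the median of the 23 T cell markers outside the thymus list was −2.03 with the level of rag1 and rag2 as a covariate and −2.14 without it. They argue against libraries of low TMM factor (−2.35 without them). Whether other cells were diluted evenly by new RNA could not be decided, since the outcome depends on the lists compared. In 4 of 4 lists picked after the result the lower quartile (neutrophil −0.60, macrophage −1.11, endothelial −0.80, thrombocyte −0.55) lay above the upper quartile of the T cell markers (−1.48). In ionocyte (−1.74), B and plasma (−1.60), dendritic (−1.52) and mast cell and eosinophil markers (−1.82) it lay below. Fewer lymphocytes in the infected gill and lower transcript levels in each cell both stay open as effects of infection, and neither was tested.

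The 82 ribosomal protein genes lay lower on inulin in uninfected fish, with a median of −0.31 over all libraries, where edgeR called 0 of them (3 at an unadjusted p under 0.05), DESeq2 0 and limma voom 63 (camera adjusted p = 8.76e-14, adjusted p = 0.799 with an estimated correlation), and −0.47 without the 6 libraries of low TMM factor, where edgeR called 77. The tables argue against library round as the whole source of the latter value, since the median was −0.44 in first-round libraries with a factor of at least 0.9 (55 called), but with round as a covariate over all libraries it was −0.21 and edgeR called 0 (0 at an unadjusted p under 0.05). The choice of libraries by TMM factor stays open, since with that factor as a covariate the median was −0.23 (quartiles −0.28 and −0.17) with 11 called. The share of counts from these genes followed the factor within groups over 37 libraries (Pearson r = −0.91, Spearman rho = −0.77, permutation p = 1e-05 for each, the smallest possible, and r = −0.87 without the 2 libraries farthest from the median factor). Share and factor come from the same counts, and a larger share of some genes lowers the rest, so this correlation is partly built in. Leaving out libraries of low factor thus tends to leave out those with a high share of these genes. In infected fish the median was 0.17 over all libraries, with the direction turned at −0.32 without the 6 libraries, −0.30 in limma voom and −0.09 with 1 surrogate variable. RNA quality, which could lower these transcripts in some libraries, and the diet itself stay open and were not tested.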

How the results depend on the processing

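The fits without 6 libraries of low TMM factor, without inulin diet infected library 2, without control diet uninfected library 9, without 9 libraries with heart transcripts and with halved counts were chosen only after the data were seen, and the others were planned. Counts of genes changed by infection were the stable part, from 7259 to 10790 on control diet and 5592 to 10009 on inulin over all settings except stricter thresholds. At a false discovery rate of 0.01 they were 6450 and 5604, and with a 2-fold threshold 4388 and 3546 genes were left, and 4562 averaged over diets. The infection effects of named genes held their direction and side of the threshold in 781 of 792 comparisons on control diet and 742 of 756 on inulin. Counts for inulin depended on the libraries and the tool, as the values here show, and for these the cause was not tested except where a stricter threshold by itself leaves fewer genes. Depth was similar in all groups and limits genes of a few counts, such as tnfa, ifng1 and hamp.

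For inulin in uninfected fish (104 genes), 29 genes passed without the 6 libraries listed out of number order, 56 with library round, 907 without libraries of low TMM factor, 64 without control diet uninfected library 9 and 21 without libraries with heart transcripts. DESeq2 called 293, limma voom 897 and edgeR with 1 surrogate variable 258, and 33 passed at 0.01 and 46 with a 2-fold threshold. In infected fish (4 genes) the counts were 771 without libraries of low TMM factor and 9 with halved counts. Without library 2 of the inulin diet infected fish edgeR called 0 (1731 at an unadjusted p under 0.05), as it did without libraries with heart transcripts (1709). There DESeq2 called 203, limma voom 1040 and the surrogate variable fit 86 over all libraries, a fit of the compared groups alone 2, a 2-fold threshold 2 and a threshold of 0.01 0 (1987 at an unadjusted p under 0.05). Averaged over infection states (76 genes) the counts were 35 with library round, 40 without the libraries out of order, 2212 without low TMM factors, 26 without heart transcripts, 386 with DESeq2, 2442 with limma voom, 407 with the surrogate variable, 27 at 0.01 and 16 with a 2-fold threshold. For the interaction (6 genes) they were 2 without the libraries out of order, 22 without low TMM factors, 3 without heart transcripts, 90 with DESeq2, 25 with limma voom, 22 with the surrogate variable and 1 at 0.01.

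With an estimated correlation, camera called 1 list for infection on control diet and 2 on inulin, and 0 in each of the other 5 contrasts, where the preset correlation called 12 to 25. With fry, 10 lists passed for inulin in uninfected fish, 0 in infected fish and 0 averaged over infection states, 32 for infection averaged over diets and 7 for the interaction. For inulin in uninfected fish 11 lists passed by camera without libraries with heart transcripts. The correlation of infection effects between the diets (0.798) was 0.547 without a filter on low counts, where the added genes have few counts, 0.704 without libraries with heart transcripts, and 0.89 over genes called in the averaged contrast.

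The replicate numbers did not pair the libraries. Of 54 same-numbered pairs 23 had a correlation of deviations over 0.1, and 5 of 37 libraries matched best with one of their own number. With the replicate block 8324 and 7307 genes passed for infection on control diet and on inulin, 52 for inulin in uninfected fish, 1 in infected fish, 47 averaged over infection states and 4 for the interaction.

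Signs turned only for named genes that did not pass in the fit of all libraries, and the cause was not tested. For infection, tnfa on control diet was 0.32 in limma voom, and ifng1 on inulin 0.03 with the replicate block and 0.42 in limma voom. For inulin in uninfected fish, il1b was 0.00 with median-ratio scaling and in DESeq2, 0.08 without low TMM factors, 0.04 without heart transcripts, 0.14 in limma voom, 0.07 without control diet uninfected library 9 and 0.01 in the compared groups alone. There cxcl8a was 0.14 without heart transcripts and 0.03 without that library 9, il13 0.06 without low TMM factors, and hamp −0.14 without low TMM factors and −0.08 in limma voom. For inulin in infected fish, tnfa was −0.29 in limma voom, mpx −0.05 with the replicate block and −0.16 without heart transcripts, ifng1 0.04 without heart transcripts and ighm 0.07 without the libraries out of order. The gene mmp9 was −0.02 with the block, −0.05 with library round, −0.04 without low TMM factors, −0.23 without library 2, −0.04 in limma voom and −0.05 with the surrogate variable.

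Of the passing genes named, 42 of 44 passed in every setting for infection on control diet, 39 of 40 on inulin, 8 of 31 for inulin in uninfected fish, 0 of 4 in infected fish and 0 of 6 for the interaction, and none changed direction. For infection on control diet, il4 did not pass without the filter (1.49), without the libraries out of order (1.13), without low TMM factors (1.32) and in the compared groups alone (1.48), and rag1 not with the block (−2.94), without the libraries out of order (−4.25) and in limma voom (−2.57).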

Other observations

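The gene families and the genes without a symbol in this part were chosen after their values were seen, and the splits for inulin in uninfected fish were set up after their first result was known.

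Of 10 gene families, most of those for RNA and protein turnover were higher with infection. Of 33 RNA polymerase subunit genes, 30 rose on control diet (median 1.02) and 27 on inulin (median 0.86), and 0 fell. For them the camera adjusted p was 1.79e-15 and 5.22e-14 in that order, and adjusted p = 0.0222 and 0.0297 with an estimated correlation. All 10 genes of the small subunit processome, the utp family that assembles ribosomes, rose on both diets, with medians of 1.25 and 1.06. Camera gave an adjusted p of 2.17e-13 and 1.25e-10, and adjusted p = 0.0222 and 0.0297 with an estimated correlation. Of 10 RNA exosome genes 9 rose on each diet, with medians of 1.21 and 1.07. The adjusted p by camera was 3.89e-08 and 2.32e-07, and adjusted p = 0.0228 and 0.0383 with an estimated correlation. All 47 tested proteasome genes rose on control diet (median 1.08) and 45 on inulin (median 1.02), with a camera adjusted p of 2.08e-19 and 3.08e-19, and adjusted p = 0.0779 and 0.0765 with an estimated correlation. Of 76 mitochondrial ribosomal protein genes 61 rose on control diet (median 0.70) and 74 on inulin (median 0.85), with a camera adjusted p of 2.85e-13 and 1.47e-16, and adjusted p = 0.231 and 0.167 with an estimated correlation. Of 82 ribosomal protein genes 1 rose and 0 fell on control diet (median 0.22), which did not pass (camera adjusted p = 0.0636, adjusted p = 0.773 with an estimated correlation). Without the 6 libraries of low TMM factor 43 rose (median 0.27), in limma voom 32 (0.26) and with 1 surrogate variable 29 (0.20), and 2 fell in each. On inulin 70 rose and 1 fell (median 0.70, camera adjusted p = 1.07e-07, adjusted p = 0.407 with an estimated correlation), with medians of 0.43, 0.46 and 0.36 in the same 3 settings, where 74, 77 and 67 rose. Whether these effects differed between the diets was not tested for the families. The other families were ddx helicases (24 and 22 of 31 up on the respective diets, 2 down on each), cct chaperonins (8 and 7 of 8 up) and translation initiation eif genes (42 and 45 of 65 up, 3 and 2 down). Collagen genes went the other way. Of 52, 35 fell on control diet (median −1.32) and 30 on inulin (median −0.97), and 0 rose, with a camera adjusted p of 5.81e-08 and 2.97e-08, and adjusted p = 0.0779 and 0.0765 with an estimated correlation. The direction of the medians of all 10 families with infection was the same with median-ratio scaling, with DESeq2, limma voom, library round or 1 surrogate variable, and without the 6 libraries of low TMM factor.

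In infected fish 8 of the 10 families lay lower on inulin than on control diet by camera, 0 of them with an estimated correlation. The median was −0.24 for RNA polymerase genes, −0.36 for utp genes and −0.30 for exosome genes. For these 3 families the camera adjusted p was 8.05e-11, 4.62e-09 and 2.21e-05 in that order, and adjusted p = 0.064, 0.064 and 0.092 with an estimated correlation. It was −0.15 for proteasome, −0.23 for cct, −0.24 for ddx, −0.11 for eif and −0.08 for mitochondrial ribosomal protein genes. These 5 families had a camera adjusted p of 1.82e-06, 0.000451, 1.13e-10, 2.66e-06 and 5.28e-05 in that order, and adjusted p = 0.443, 0.262, 0.064, 0.262 and 0.531 with an estimated correlation. Without the 6 libraries of low TMM factor the medians of the 8 families were −0.38, −0.46, −0.45, −0.40, −0.40, −0.31, −0.30 and −0.41 in the order named. Of the 76 mitochondrial ribosomal protein genes edgeR called 0 over all libraries (5 at an unadjusted p under 0.05), DESeq2 0 and limma voom 36 (median −0.35), and edgeR called 33 without the 6 libraries and 0 with 1 surrogate variable (median −0.24, 41 at an unadjusted p under 0.05). Collagen genes lay higher (median 0.17, camera adjusted p = 0.0127, adjusted p = 0.448 with an estimated correlation), at 0.06 without the 6 libraries and 0.05 with 1 surrogate variable. The ribosomal protein genes had a median of 0.17 and did not pass (camera adjusted p = 0.197). The direction of this median turned in settings given above. Of the 33 RNA polymerase genes edgeR called 0 over all libraries (12 at an unadjusted p under 0.05), DESeq2 2 and limma voom 17, and edgeR called 13 without the 6 libraries of low TMM factor.

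Some uninfected fish of the inulin diet had transcripts that marked infected fish. The gene loc100005129 (ENSDARG00000116187) had 0 to 1.5 CPM in control diet uninfected fish and 44.6 to 1134 CPM in control diet infected fish. In inulin diet uninfected fish it exceeded 10 CPM in 5 of 10, up to 224 CPM. The gene ENSDARG00000109271, which shares the name loc569153 with another gene of the deposited table, had 0 to 7.1 CPM and 102 to 2970 CPM in the same control diet groups, and exceeded 10 CPM in 5 of 10 inulin diet uninfected fish, up to 405 CPM. In these 10 fish teni.1 reached at most 9.63 CPM, jac2 at most 0.425 CPM and mmp13a at most 3.61 CPM, against group medians of 175, 53.9 and 208 CPM in control diet infected fish. No explanation was tested.

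Transcripts of other tissues, in CPM without TMM factors, stood out in single libraries. The heart gene myl7 reached 2217 CPM in control diet uninfected library 4 and 2474, 1964, 1923 and 1173 CPM in inulin diet uninfected libraries 5, 4, 9 and 3. The thymus gene rag1 reached 316 CPM in control diet uninfected library 1 and 124 CPM in inulin diet uninfected library 8. The pituitary hormone gene prl reached 187 CPM in inulin diet infected library 2, and gh1 239 CPM in control diet infected library 5.

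By the 100 splits chance was excluded at 0.05 for the genes changed by infection. On control diet 8589 genes passed, against 5125 in the highest other split, on inulin 7868 against 2840, and averaged over diets 11133 against 616, and 1 of 100 splits reached the real count each time. For inulin in uninfected fish 104 genes passed against 92, in infected fish 4 against 2, and averaged over infection states 76 against 6, again with 1 of 100 splits. In uninfected fish the other splits of many genes followed a structure of the samples. Of the 5 uninfected libraries with myl7 above 10 CPM 4 were on inulin. The 6 other splits with all 5 on one side gave 0 to 92 genes. With all 5 on the control diet side the counts were 76, 89 and 92, and with all 5 on the inulin side each count was 0. The 93 other splits with these mixed gave at most 3. Without the 9 libraries with heart transcripts all 104 genes kept their direction and 21 passed.

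Without the 6 libraries of low TMM factor, inulin changed 907 genes in uninfected fish, against 194 in the highest other split (1 of 100 reached the real count), and 2212 averaged over infection states against 166 (1 of 100). In infected fish 771 genes passed against 1323, and 2 of 100 splits reached the real count. What set the higher split apart was not tested. These splits regrouped the remaining libraries and did not repeat the choice of the 6, which was made after the data were seen. They therefore cannot exclude chance for the counts without the 6 libraries. For gene lists by camera the splits bear on the count of lists and not on any single list. Chance was excluded at 0.05 for the count in infection on control diet, with 25 lists against 27 in the highest other split (3 of 100). It could not be excluded for infection on inulin (19 against 25, 18 of 100), infection averaged over diets (20 against 25, 14 of 100) or inulin in uninfected fish (22 against 27, 5 of 100). Nor could it for inulin in infected fish (12 against 22, 36 of 100) or averaged over infection states (12 against 29, 53 of 100).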
